A study of Mus musculus with 18 samples.

How the data were processed

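RNA-seq libraries were made from 3 innate lymphoid cell populations sorted from the small-intestinal lamina propria of mice, NKp46+ ILC3, CCR6+ ILC3 and ILC2. Each population came from mice whose Maf alleles were intact (WT) and from mice whose floxed Maf alleles were deleted by Cre recombinase expressed from the Il7r gene (KO), with 3 libraries in each of 6 groups. Per the labels' protocols, all cells were negative for CD3 and CD19 and positive for CD127, the product of Il7r. The ILC3 gates also took cells with high CD90, the product of Thy1, that lacked KLRG1 and carried either NKp46, the product of Ncr1, or CCR6. The ILC2 gate took KLRG1-positive cells. Libraries were made with a low-input kit of which the labels give 2 versions, without saying which library used which. The mice had an incomplete backcross to C57Bl/6, per the labels, and the labels do not say whether the 3 libraries of a group came from separate mice. All p-values therefore measure only the spread between these samples, which may be technical.

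The authors deposited unnormalised counts of reads per gene, 1 file per library. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.4.1a to the mouse genome build GRCm38 and counted with featureCounts 1.4.6-p4 on the GENCODE vM13 annotation. Per the file headers, the counting did not use strand, so reads of overlapping or antisense genes cannot be told apart. The notes also name DESeq2 1.22.0 and R 3.5.1, and no output of these was used here. The files held 50600 gene identifiers. Symbols and coordinates were taken by identifier from the GENCODE vM21 annotation of the same build, which matched 50376 identifiers and left 224 without a symbol, and 136 identifiers shared a symbol with another. Families with similar sequences, such as the Klr receptors, the granzymes, the T cell receptor gamma constant genes and the immunoglobulins, can exchange reads between members, and single members of them are uncertain.

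Library totals ran from 22241820 to 32613357 counts. Of all identifiers, 15237 had no count in any library and 19171 others were removed by edgeR's expression filter, which left 16192 genes. Counts were scaled with TMM factors in edgeR 4.0.16 under R 4.3.3, and levels are given as normalised CPM, the usual depth-scaled count, mean ± SD over 3 libraries. A quasi-likelihood model with robust dispersion was fitted to all 18 libraries with 1 mean per group, and the common dispersion of 0.2021 corresponds to a coefficient of variation of 45.0%. Log2 fold changes come from this fit with edgeR's default prior count. Each SE is the absolute change divided by the square root of its F statistic. A prior count of 2 was used only for log2 CPM. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The sequenced reads carry no molecular identifiers, so limits set by counting cover counting error only.

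The comparisons were KO against WT within each subset, the differences of the KO effect between each pair of subsets, WT NKp46+ against WT CCR6+ ILC3, and WT ILC2 against the mean of both WT ILC3 subsets. The samples, tests, named-gene rule and alternatives were fixed, except where said otherwise, before the data were examined. Maf was reported first, in every library. For each KO comparison the text may name the 10 genes in each direction with the smallest p among those with an adjusted p under 0.05, an absolute log2 change of at least 1, a mean of at least 5 CPM, and all 3 KO libraries above or below all 3 WT libraries. Chance alone gives such a separation to 10% of genes. For the other comparisons 5 genes per direction were taken, without the separation condition for the differences. Up to 4 members of each list with the smallest p, the gating genes and Maf were always eligible. Predicted genes without a usual name were passed over. Genes named outside this rule are said to be so, apart from called members of the lists and genes named in the tests of strain segments and of NKp46+ ILC3 within the KO sorts.

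A fixed set of 26 gene lists covered the type 1 program, cytotoxic and NK receptor genes, the type 3 program, LTi and CCR6+ ILC3 genes, the type 2 program, Maf-associated coinhibitory and cytokine genes of T cells, MHC class II presentation, naive-like and TCF1-associated genes, the Notch pathway, immediate early and dissociation stress genes, proliferation, the interferon response, glycolysis and hypoxia, cholesterol synthesis, tissue residency and gut homing, ribosomal protein genes, mitochondrially encoded genes, sex-linked genes and the gating genes. It also held markers of T cells, B and plasma cells, myeloid cells, mast cells, epithelium, stroma and endothelium, and erythroid cells. Lists were tested against all other genes with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, and p-values were adjusted over the lists of a comparison. Camera was repeated with an estimated correlation. The fry test, which asks whether a list's genes move one way without comparing them with other genes, was an alternative. Lists were also counted by the genes called over all genes and by those called when p-values were adjusted over the list alone. Overlaps of calls were tested with Fisher's two-sided exact test.

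The code was tested on simulated counts with 200 genes changed by known amounts. In the KO comparison of NKp46+ ILC3, edgeR recovered 58% of changes of log2 1 and 89% of changes of log2 2, with 4.55% false calls. The recovery was 54% and 92% with 6.41% false calls in CCR6+ ILC3, and 60% and 98% with 3.66% in ILC2. On the same simulated data DESeq2 made 24.3% to 25.5% false calls in the 3 KO comparisons. The simulated counts were drawn with the spread that edgeR had estimated, so these rates do not rank the methods on the real libraries. Camera called the simulated changed list and no unchanged list.

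Alternatives were relative log expression scaling, scaling to library totals, no expression filter or a stricter one of 5 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, an adjusted p under 0.01, an added minimum change, and leaving out each library in turn. Leaving out libraries for the list tests and for the overlap between subsets was added after seeing the data. No library was left out of the main comparisons, and no pair of replicates held identical values or agreed within sampling noise, with a chi-square per gene of 40.0 to 91.2. Splicing, isoforms and the deleted exons themselves were not analysed here.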

Results

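Gene expression was measured by RNA-seq in 3 subsets of innate lymphoid cells (ILCs), lymphocytes that lack rearranged antigen receptors, from the lamina propria of the mouse small intestine. NKp46+ ILC3 and CCR6+ ILC3 belong to the group that expresses Rorc and makes interleukins such as the product of Il22, and ILC2 to the group that expresses Gata3 and makes type 2 cytokines. Each subset was sorted from cohoused WT and Maf KO mice that both carried Cre recombinase in the Il7r gene, and each of the 6 groups had 3 libraries. The design asks how gene expression in each subset differs in mice that lack the transcription factor c-Maf, the product of Maf, in cells expressing Il7r. It cannot tell an effect of the loss within the sorted cells from an effect of the loss in other such cells. The 18 libraries held 22241820 to 32613357 counts each, and levels are given as normalised CPM, the usual depth-scaled count, mean ± SD. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over 16192 genes, with n = 3 libraries per group.

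Maf (ENSMUSG00000055435.6, GRCm38 chromosome 8, 115682942 to 115707794, minus strand) was nearly absent from every KO library. In NKp46+ ILC3 the WT libraries held 123, 115 and 115 CPM and the KO libraries 0.163, 0.246 and 0.0936 CPM. In CCR6+ ILC3 the levels were 120, 116 and 85.6 CPM in WT and 0.520, 0.494 and 1.04 CPM in KO. In ILC2 they were 78.9, 55.6 and 58.1 CPM in WT and 0.299, 0.511 and 1.46 CPM in KO. Maf fell by 9.37 ± 0.54 (log2, SE; adjusted p = 2.17e-07) in NKp46+ ILC3, by 7.28 ± 0.48 (adjusted p = 1.12e-06) in CCR6+ ILC3 and by 6.41 ± 0.46 (adjusted p = 6.37e-06) in ILC2. Every library therefore carried the Maf level that its label names.

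**Figure D1:**
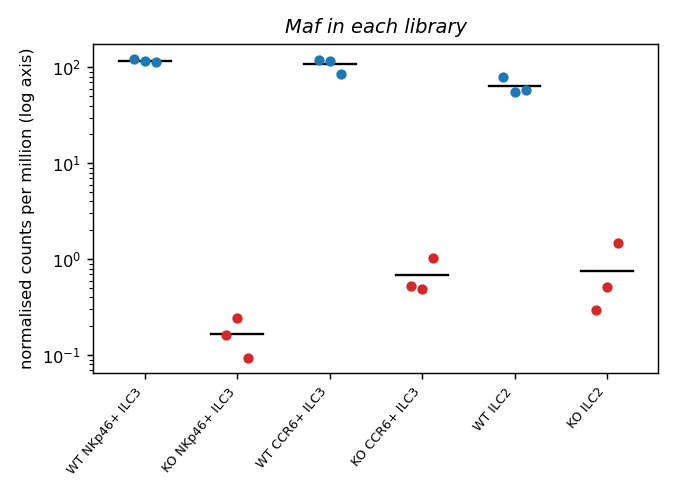
Maf in normalised CPM on a log axis, in each of the 18 libraries; blue points are WT, red points are KO and black lines are group means. WT libraries lie between 55.6 and 123 CPM and KO libraries between 0.0936 and 1.46 CPM.

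The WT ILC3 subsets differed most in the genes of the type 1, cytotoxic and lymphoid tissue inducer programs. Ncr1, which encodes NKp46, was at 473 ± 97.3 CPM in NKp46+ cells and 5.70 ± 2.17 CPM in CCR6+ cells, and Ccr6 was at 2.19 ± 0.452 and 538 ± 37.5 CPM. Tbx21, the gene of the type 1 transcription factor T-bet, was higher in NKp46+ cells by 6.45 ± 0.58 on the log2 scale (adjusted p = 4.15e-06), and Xcl1, a chemokine gene, by 8.47 ± 0.59 (adjusted p = 1.59e-07). Ctsw, which encodes a lymphocyte cathepsin, was at 541 ± 79.8 against 8.90 ± 1.39 CPM. CCR6+ cells held more Cd4 (log2 difference -4.00 ± 0.41, adjusted p = 8.46e-06), Nrp1 (-3.29 ± 0.36) and the cytokine gene Il17f (-3.53 ± 0.48). Maf did not differ detectably between the WT subsets (0.13, adjusted p = 0.859).

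Of 23 type 1 genes, 20 were higher in WT NKp46+ cells (21 adjusted over the list alone), as were 21 of 25 cytotoxic and NK receptor genes (22 alone). Of 15 LTi and CCR6+ ILC3 genes, 11 were lower. Camera called these lists at adjusted p = 2.96e-19, 3.77e-22 and 1.4e-08, and at 0.000755, 0.00271 and 0.00844 with an estimated correlation. In all, 2745 genes differed, 1548 higher and 1197 lower in NKp46+ cells. The higher share was 56.4%, and 46.3% when libraries were scaled to their totals, and with an absolute log2 difference of at least 1 there were 578 higher and 692 lower genes.

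WT ILC2 differed from the ILC3 subsets by Gata3, the gene of the transcription factor of type 2 lymphocytes, at 1785 CPM against 154 ± 16 in NKp46+ and 176 ± 23.2 in CCR6+ ILC3 (log2 difference 3.44 ± 0.11, adjusted p = 2.91e-12). Klrg1, the gating gene, was at 846 ± 60.8 against 9.73 ± 1.42 and 3.04 ± 0.879 CPM. Deptor, whose product inhibits the kinase mTOR, was higher by 5.23 ± 0.13 (adjusted p = 7.67e-13), and the Notch target Hes1 by 3.88 ± 0.14 (adjusted p = 6.75e-12). Rorc was lower by a log2 difference of -5.19 ± 0.34 (adjusted p = 1.33e-08) and Il22 by -7.02 ± 0.64 (adjusted p = 1.04e-06). All 22 measured type 2 genes were higher in ILC2 (camera adjusted p = 3.71e-21, and 7.11e-05 with an estimated correlation). Of 15 LTi and CCR6+ ILC3 genes, 13 were lower and 1 higher (camera adjusted p = 8.56e-08, and 0.0185 with an estimated correlation). In all 5230 genes differed, 2614 higher and 2616 lower in ILC2, a balance that was 2790 and 2338 with scaling to library totals and 1078 and 1456 with an absolute log2 difference of at least 1.

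In Maf KO NKp46+ ILC3, 4 of 25 cytotoxic and NK receptor genes rose and 5 of 14 cholesterol synthesis genes fell. Klri2, a killer cell lectin-like receptor gene, was at 72.2 ± 9.65 CPM in WT and 493 ± 50.3 CPM in KO (log2 change 2.77 ± 0.50, adjusted p = 0.00942). Nkg7, which encodes a cytotoxic granule protein, rose by 1.33 ± 0.28 (adjusted p = 0.0186), Klrc2 by 1.66 ± 0.38 (adjusted p = 0.0324) and Slamf7 by 1.20 ± 0.29 (adjusted p = 0.0427). No member of the first list fell (10 rose when adjusted over the list alone), and camera called the list at adjusted p = 2.6e-09, which became adjusted p = 0.0772 with an estimated correlation. Single calls depended on single libraries. Klri2 lost its call without WT replicate 1 or 2 (highest adjusted p = 0.0601), Nkg7 without WT replicate 1 or 3 or KO replicate 1 or 2 (0.0864), and Klrc2 and Slamf7 without any library but WT replicate 2 (0.154 and 0.191). Without the expression filter, Nkg7, Klrc2 and Slamf7 were at adjusted p = 0.0837, 0.0837 and 0.147.

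No cholesterol synthesis gene rose with the 5 that fell (10 fell when adjusted over the list alone). Srebf2, the gene of the transcription factor that drives the pathway, went from 259 ± 19.3 to 134 ± 13.6 CPM (log2 change -0.95 ± 0.11, adjusted p = 0.000261). Idi1 changed by -1.56 ± 0.26 (adjusted p = 0.00351), Ldlr, the low-density lipoprotein receptor gene, by -0.85 ± 0.15 (adjusted p = 0.00654) and Msmo1 by -0.75 ± 0.12 (adjusted p = 0.00274). The list had a camera adjusted p = 2.86e-11, and an adjusted p = 0.0555 with an estimated correlation.

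Outside these lists, the genes with the smallest p that fell in KO NKp46+ ILC3 were Ffar2, which encodes a receptor for short-chain fatty acids (chromosome 7, 30818348 to 30823775), and Tmem64 (chromosome 4, 15265831 to 15286753). Ffar2 went from 91.7 ± 4.29 to 12.5 ± 1.39 CPM (log2 change -2.87 ± 0.17) and Tmem64 from 817 ± 72.1 to 326 ± 5.51 CPM (-1.32 ± 0.08), both at adjusted p = 2.17e-07. Podnl1 (chromosome 8, 84125989 to 84132527) changed by -3.02 ± 0.23 (adjusted p = 2.91e-06), Sema4b by -1.92 ± 0.17 (adjusted p = 1.07e-05), and Icos, a costimulatory receptor gene, by -1.50 ± 0.16 (adjusted p = 0.00012). Of the rising genes, Swap70 had the smallest p (0.88 ± 0.08, adjusted p = 1.51e-05), a gene below the minimum change of 1 for naming and named after its values were seen. Among those above this minimum with the smallest p were Bmp2, a bone morphogenetic protein gene (chromosome 2, 133552159 to 133562885; log2 change 2.07 ± 0.20, adjusted p = 5.34e-05), Pheta2 (1.81 ± 0.19), Serpine2, a protease inhibitor gene (2.18 ± 0.23), Apobec1 (1.18 ± 0.13) and Cntn1 (2.10 ± 0.25).

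Of 18 type 3 genes 1 fell, Blk, a Src-family kinase gene, from 17.7 ± 1.51 to 0.401 ± 0.409 CPM (log2 change -5.51 ± 0.65, adjusted p = 0.000308), and none rose (1 rose and 2 fell when adjusted over the list alone). Il22 was at 1744 CPM in WT and 636 ± 231 CPM in KO and was not called (-1.46 ± 0.51, adjusted p = 0.227), nor was Il17f (-1.84 ± 0.46, adjusted p = 0.0633). Of 15 LTi and CCR6+ ILC3 genes 2 fell, Ffar2 and the cytokine gene Tnfsf11 (-1.27 ± 0.24, adjusted p = 0.0103), while 3 rose and 5 fell when adjusted over the list alone. Camera called the type 3 list at adjusted p = 0.0337 and the LTi list at 0.0402, both with adjusted p = 0.422 with an estimated correlation. Both calls ended without WT replicate 2 or 3 or KO replicate 1 or 2 (highest adjusted p = 0.0874 and 0.133), and the LTi call also with only the groups compared (0.105) and with the replicate block (0.0713). Of 23 type 1 genes 1 rose, the transcription factor gene Runx3 (0.30 ± 0.06, adjusted p = 0.0199), and 1 fell, the interleukin receptor gene Il12rb1 (-0.77 ± 0.15, adjusted p = 0.0116), and the list was not called (camera adjusted p = 0.173). Runx3 lost its call without WT replicate 1 or 3 or KO replicate 1 or 2 (highest adjusted p = 0.119), with only the groups compared (0.138) and without the filter (0.12), and Il12rb1 lost its call without KO replicate 2 (0.0601). Ifng, the interferon gamma gene, was at 168 ± 34.4 CPM in WT and 515 ± 98.9 CPM in KO and was not called (1.61 ± 0.53, adjusted p = 0.185). Its libraries did not overlap, at 151, 208 and 146 CPM in WT and 565, 578 and 401 CPM in KO. Nor did those of Tbx21, also not called, at 346, 424 and 272 CPM in WT and 569, 565 and 603 CPM in KO. Type 1 genes together took 0.667 ± 0.0148% of counts in WT and 0.828 ± 0.00542% in KO. The fit estimates the spread of a gene over all 6 groups, and a missing call does not show that these genes stayed level.

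Among the other lists in NKp46+ ILC3, 1 of 22 type 2 genes rose and 3 fell (Icos, Cysltr1 and Lif), with Dgat2, an enzyme gene of triglyceride synthesis, up by 2.10 ± 0.31 (adjusted p = 0.00169) and the list at camera adjusted p = 0.993. Of 16 residency and gut homing genes, Itga4, an integrin gene, fell by 1.07 ± 0.19 (adjusted p = 0.00596) and the gut homing chemokine receptor gene Ccr9 by 0.85 ± 0.17 (adjusted p = 0.0152). That list was at camera adjusted p = 0.987, and Ccr9 lost its call without WT replicate 1 or 3 or KO replicate 1 or 2 (highest adjusted p = 0.072). Hes1 was the 1 Notch gene of 8 that fell (-1.19 ± 0.16, adjusted p = 0.000787; list 0.697), and Usp18 the 1 interferon response gene of 24 that rose (1.47 ± 0.20, adjusted p = 0.000775; list 0.905). The proliferation, glycolysis and erythroid lists had no called member, but camera called them at adjusted p = 0.00461, 0.0257 and 0.0402, which became 0.600, 0.422 and 0.600 with an estimated correlation. The proliferation call ended without WT replicate 2 or KO replicate 2 (highest adjusted p = 0.0717), the glycolysis call without WT replicate 2 or KO replicate 1 (0.0772), and the erythroid call without WT replicate 1 or 2 or KO replicate 1 (0.974). With the fry test these lists were at adjusted p = 0.287, 0.0884 and 0.341, and with only the groups compared the glycolysis and erythroid lists were at 0.0534 and 0.158. The erythroid list was at 0.0527 with the replicate block.

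In all, 322 genes were called in KO NKp46+ ILC3, 129 higher and 193 lower. The count was 176, 202 and 187 without WT replicate 1, 2 and 3, and 205 without KO replicate 2. None of the gating genes was called, with Ncr1 at 473 ± 97.3 CPM in WT and 654 ± 63.5 CPM in KO (adjusted p = 0.855). B and plasma cell markers took 3.77 ± 2.06% of counts in WT and 2.08 ± 0.497% in KO libraries, a list not called (camera adjusted p = 0.113), with Igha, an immunoglobulin gene, the largest single gene in WT replicate 2 at 3.84% of counts. Cpa3, a mast cell protease gene, rose from 2.53 ± 0.343 to 29.1 ± 6.98 CPM (log2 change 3.52 ± 0.58, adjusted p = 0.00347), 1 of 2 measured mast cell markers.

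**Figure D2:**
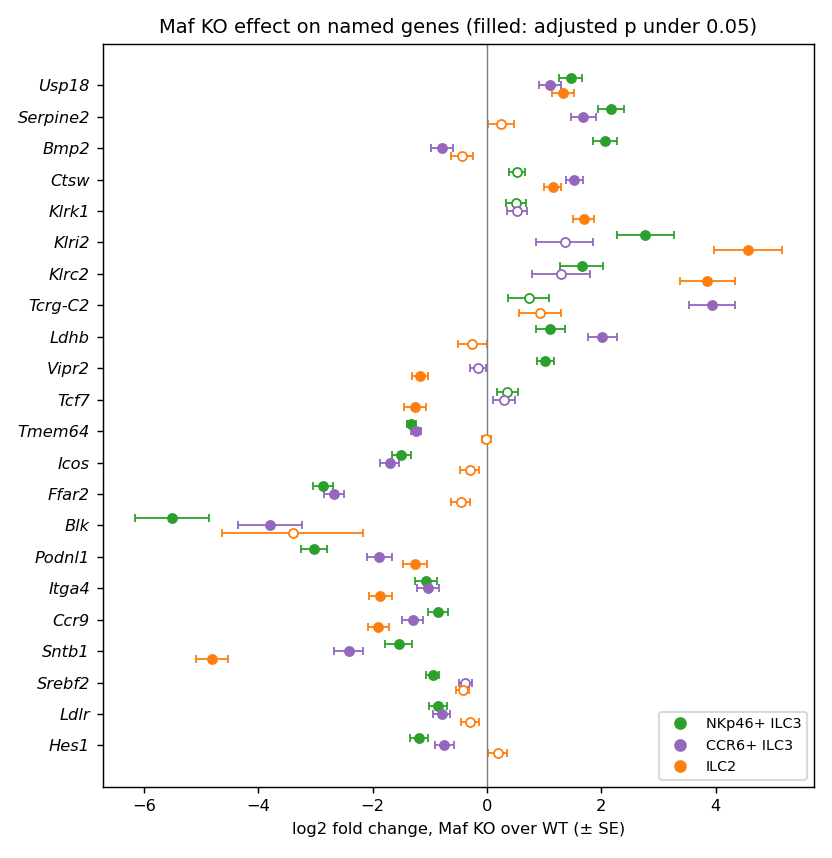
Log2 fold change of KO over WT with its standard error (n = 3 libraries per group) for 22 genes, in NKp46+ ILC3 (green), CCR6+ ILC3 (purple) and ILC2 (orange); filled points have an edgeR adjusted p under 0.05. Ffar2 and Tmem64 are filled below zero in both ILC3 subsets, and Ccr9, Itga4 and Sntb1 in all 3 subsets.

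In Maf KO CCR6+ ILC3, Ffar2, Tmem64 and Icos also fell, as did 3 of 22 type 2, 2 of 8 Notch and 3 of 14 cholesterol synthesis genes. Ffar2 went from 85.9 ± 7.07 to 13.4 ± 1.57 CPM (log2 change -2.68 ± 0.17, adjusted p = 8.04e-07), Tmem64 from 452 ± 17.2 to 191 ± 11 CPM (-1.24 ± 0.08, adjusted p = 8.04e-07) and Icos from 140 ± 17.2 to 43.1 ± 9.44 CPM (-1.70 ± 0.17, adjusted p = 5.75e-05). Relt, a tumour necrosis factor receptor family gene, changed by -1.64 ± 0.15 (adjusted p = 4.26e-05), Pvrig, an inhibitory receptor gene, by -4.73 ± 0.44 (adjusted p = 4.52e-05) and Ptprv by -3.27 ± 0.35. The rising genes with the smallest p were Ctsw (chromosome 19, 5465240 to 5468498), from 8.90 ± 1.39 to 25.7 ± 1.31 CPM (log2 change 1.53 ± 0.15, adjusted p = 6.6e-05), and the T cell receptor constant gene Tcrg-C2, from 2.95 ± 0.953 to 45.3 ± 4.56 CPM (3.94 ± 0.40, adjusted p = 6.6e-05). Another T cell receptor gene, Trdc, fell from 2.39 ± 0.744 to 0.483 ± 0.350 CPM (-2.29 ± 0.42, adjusted p = 0.00886), the 1 called gene of 11 T cell markers (list 0.544). It was at 0.148 with only the groups compared. Ldhb, a lactate dehydrogenase gene, rose by 2.02 ± 0.26 (adjusted p = 0.000539), Serpine2 by 1.69 ± 0.22 (adjusted p = 0.000714) and Spp1, the osteopontin gene, by 5.98 ± 0.92 (adjusted p = 0.00376). Spp1 was not called with only the groups compared (adjusted p = 0.0886).

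Of 22 type 2 genes 3 fell in KO CCR6+ ILC3 and none rose (5 fell when adjusted over the list alone). They were Icos, Il17rb, the gene of an interleukin receptor subunit (-2.22 ± 0.38, adjusted p = 0.00685), and the transcription factor gene Bcl11b (-1.62 ± 0.33, adjusted p = 0.0212). Of 8 Notch genes 2 fell (4 alone), Hes1 (-0.74 ± 0.16, adjusted p = 0.0255) and Dtx1 (-0.82 ± 0.18, adjusted p = 0.0261). Of 14 cholesterol synthesis genes 3 fell (5 alone), Ldlr (-0.79 ± 0.15, adjusted p = 0.013), Insig1 (-0.75 ± 0.15, adjusted p = 0.017) and Cyp51 (-0.79 ± 0.16, adjusted p = 0.0196). Camera called the type 2 and Notch lists at adjusted p = 0.000641, both with adjusted p = 0.0831 with an estimated correlation, and the cholesterol list at 6.87e-05, with adjusted p = 0.210 with an estimated correlation. Single members lost their calls without 1 library. These were Bcl11b without WT replicate 2 or 3 or KO replicate 1 or 2 (highest adjusted p = 0.0925), Hes1 without WT replicate 2 or 3 or KO replicate 1 or 3 (0.136), Dtx1 without WT replicate 2 or 3 or KO replicate 2 (0.139), Ldlr without WT replicate 3 or KO replicate 2 (0.0812), Insig1 without WT replicate 2 or KO replicate 1 (0.0848) and Cyp51 without WT replicate 3 or KO replicate 1 (0.0857). With only the groups compared, Bcl11b (0.169), Hes1 (0.131), Dtx1 (0.134), Insig1 (0.0712) and Cyp51 (0.0878) were not called, nor were Bcl11b (0.0739) and Dtx1 (0.0763) without the filter.

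Of 25 cytotoxic and NK receptor genes 3 rose in KO CCR6+ ILC3 and none fell (5 rose when adjusted over the list alone), Ctsw, Cd226 (0.67 ± 0.13, adjusted p = 0.0156) and Klrb1a (2.42 ± 0.54, adjusted p = 0.0349). Camera called the list at adjusted p = 0.000641, which became adjusted p = 0.325 with an estimated correlation, and the fry test gave 0.0512. Cd226 lost its call without WT replicate 3 or KO replicate 1 or 2 (highest adjusted p = 0.0979) and Klrb1a without any library but WT replicate 2 (0.157). With only the groups compared Cd226 was at 0.0878 and Klrb1a at 0.131. Of 23 type 1 genes 1 rose, Runx3 (0.30 ± 0.06, adjusted p = 0.0228), and 1 fell, Il12rb1 (-1.18 ± 0.15, adjusted p = 0.000557), with the list at camera adjusted p = 0.957, and the call of Runx3 ended without any 1 of the 6 libraries (highest adjusted p = 0.147), with only the groups compared (0.134) and without the filter (0.116). Tbx21 was at 3.97 ± 0.281 CPM in WT and 13.3 ± 3.59 CPM in KO and was not called (1.74 ± 0.49, adjusted p = 0.112). Of 18 type 3 genes Blk fell (-3.79 ± 0.56, adjusted p = 0.00226) and Batf rose (0.78 ± 0.18, adjusted p = 0.0339), with the list at 0.999. Batf lost its call without any library but KO replicate 1 (highest adjusted p = 0.174) and with only the groups compared (0.0634). Of 15 LTi and CCR6+ ILC3 genes Ffar2 fell, and the list was not called (0.200).

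Of 16 residency and gut homing genes 3 fell in KO CCR6+ ILC3, Ccr9 (-1.30 ± 0.18, adjusted p = 0.000827), Itga4 (-1.03 ± 0.19, adjusted p = 0.00886) and Gpr55 (-1.78 ± 0.34, adjusted p = 0.0126). Camera called the list at adjusted p = 0.0146, which became adjusted p = 0.228 with an estimated correlation, 0.0682 without KO replicate 1 and 0.0606 with only the groups compared. Gpr55 lost its call without WT replicate 2 or 3 or KO replicate 2 or 3 (highest adjusted p = 0.0642), and with only the groups compared Ccr9 was at 0.0623 and Gpr55 at 0.0902. No member of the proliferation or ribosomal protein lists was called. Camera placed the proliferation list lower at adjusted p = 0.0151 and the ribosomal protein list higher at 0.00260, each with adjusted p = 0.728 with an estimated correlation, and fry gave 0.459 and 0.509. The proliferation call ended without WT replicate 2 or 3 or KO replicate 2 (highest adjusted p = 0.210) and the ribosomal call without KO replicate 3 (0.323). Prdm1, a transcription factor gene of the Maf-associated list, fell by 1.26 ± 0.20 (adjusted p = 0.00317), with that list at 0.106 and Prdm1 at adjusted p = 0.0739 with only the groups compared.

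In all, 303 genes were called in KO CCR6+ ILC3, 83 higher and 220 lower. The higher share was 27.4%, and 40.8% when libraries were scaled to their totals. The count was 151 and 117 without WT replicate 2 and 3, and 136 and 185 without KO replicate 2 and 3. None of the gating genes was called, with Ccr6 at 538 ± 37.5 CPM in WT and 441 ± 24.5 CPM in KO (adjusted p = 0.783). B and plasma cell markers took 4.86 ± 1.67% of counts in WT and 2.83 ± 0.476% in KO libraries, a list not called (camera adjusted p = 0.0926).

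**Figure D3:**
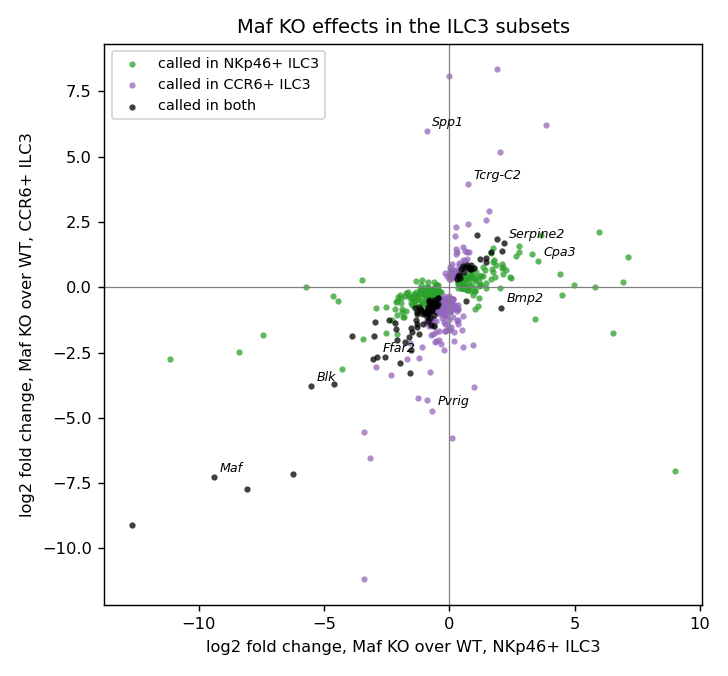
Log2 fold change of KO over WT in NKp46+ ILC3 (x axis) against CCR6+ ILC3 (y axis) for genes called by edgeR in NKp46+ ILC3 (green), in CCR6+ ILC3 (purple) or in both (black); each point is 1 gene. Of the genes called in both, 69 fell in both, 23 rose in both and 2 rose in NKp46+ ILC3 and fell in CCR6+ ILC3.

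In Maf KO ILC2, 8 of 25 cytotoxic and NK receptor genes rose, several from low levels in WT. Klrk1, the gene of the activating receptor NKG2D, went from 10.4 ± 1.98 to 33.5 ± 10.4 CPM (log2 change 1.69 ± 0.18, adjusted p = 0.000245) and Ctsw from 42.9 ± 9.50 to 95.1 ± 0.804 CPM (1.15 ± 0.15, adjusted p = 0.00139). Klri2 rose by 4.57 ± 0.60 (adjusted p = 0.00317), Klrc2 by 3.86 ± 0.48 (adjusted p = 0.00118) and the granzyme gene Gzmc by 3.05 ± 0.40 (adjusted p = 0.00213), all from under 1 CPM in WT. No member fell (11 rose when adjusted over the list alone), and the list was called at camera adjusted p = 1.18e-16, and at adjusted p = 0.0177 with an estimated correlation. With only the groups compared, Klrk1 (0.0501), Klri2 (0.2), Klrc2 (0.0568), Gzmc (0.0711) and Klrc1 (0.0646) were not called, 5 of the 6 tried. The alternatives were not run for Klrb1a and Klrb1c in ILC2. Klrc1 (2.76 ± 0.46, adjusted p = 0.0125) also lost its call without the filter (0.0509) and without WT replicate 2 or 3 (highest adjusted p = 0.0849). Genes of NKp46+ ILC3 were also mostly higher in KO ILC2. Among the 50 most abundant genes at least 16 times higher in KO NKp46+ ILC3 than in WT ILC2, 47 had a higher mean in KO than in WT ILC2, such as Car2 (16.6 and 42.5 CPM). Those not higher were Rorc (24.1 CPM in WT and 23.9 CPM in KO), Il1r1 (4.19 and 4.08 CPM) and Serinc2 (8.28 and 7.97 CPM). Choosing genes by a low level in WT ILC2 and a high level in KO NKp46+ ILC3 can itself favour such rises.

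Sntb1, which encodes a syntrophin, fell the most clearly in KO ILC2, from 49.9 ± 3.17 to 1.78 ± 0.333 CPM (log2 change -4.81 ± 0.28, adjusted p = 1.84e-07). Ccr9 (chromosome 9, 123678439 to 123784330) went from 293 ± 22.6 to 78.5 ± 11.9 CPM (-1.90 ± 0.18, adjusted p = 7.53e-05) and Itga4 changed by -1.86 ± 0.19 (adjusted p = 0.000217). Vipr2, a receptor gene for vasoactive intestinal peptide, changed by -1.17 ± 0.14 (adjusted p = 0.000981), and Tcf7, the gene of the transcription factor TCF-1, by -1.26 ± 0.19 (adjusted p = 0.00425). Cxcr6, a chemokine receptor gene, rose from 474 ± 73.1 to 902 ± 110 CPM (0.93 ± 0.14, adjusted p = 0.00413), and Usp18 also rose (1.33 ± 0.20, adjusted p = 0.00413). Of 16 residency genes 2 rose, Cxcr6 and Cd69 (0.60 ± 0.13, adjusted p = 0.0424), and 2 fell, Ccr9 and Itga4, with the list at camera adjusted p = 0.626. Cd69 lost its call without any library but KO replicate 2 (highest adjusted p = 0.183), and with only the groups compared Tcf7 (0.2), Cxcr6 (0.0501) and Cd69 (0.135) were not called, nor was Cd69 with the replicate block (0.063).

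No member of the 22 type 2 genes was called in KO ILC2 (camera adjusted p = 0.626), and Klrg1 was at 846 ± 60.8 CPM in WT and 832 ± 28 CPM in KO (adjusted p = 0.997). The type 1 list, with 1 gene called, was at camera adjusted p = 0.0523, and Ncr1 was at 6.00 ± 5.47 CPM in WT and 18 ± 11.6 CPM in KO (1.58 ± 0.64, adjusted p = 0.455). Cpa3 rose by 3.16 ± 0.60 (adjusted p = 0.0226) and lost its call without WT replicate 3 or KO replicate 1 (highest adjusted p = 0.0921) and with only the groups compared (0.221). B and plasma cell markers took 1.53 ± 0.438% of counts in WT and 2.05 ± 0.451% in KO ILC2 (camera adjusted p = 0.143). In all, 94 genes were called, 54 higher and 40 lower, a balance that was 39 and 40 with scaling to library totals, 140 and 148 with DESeq2 and 12 and 18 with only the groups compared. The count was 52 without WT replicate 2, and 54 and 59 without KO replicates 1 and 2.

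**Figure D4:**
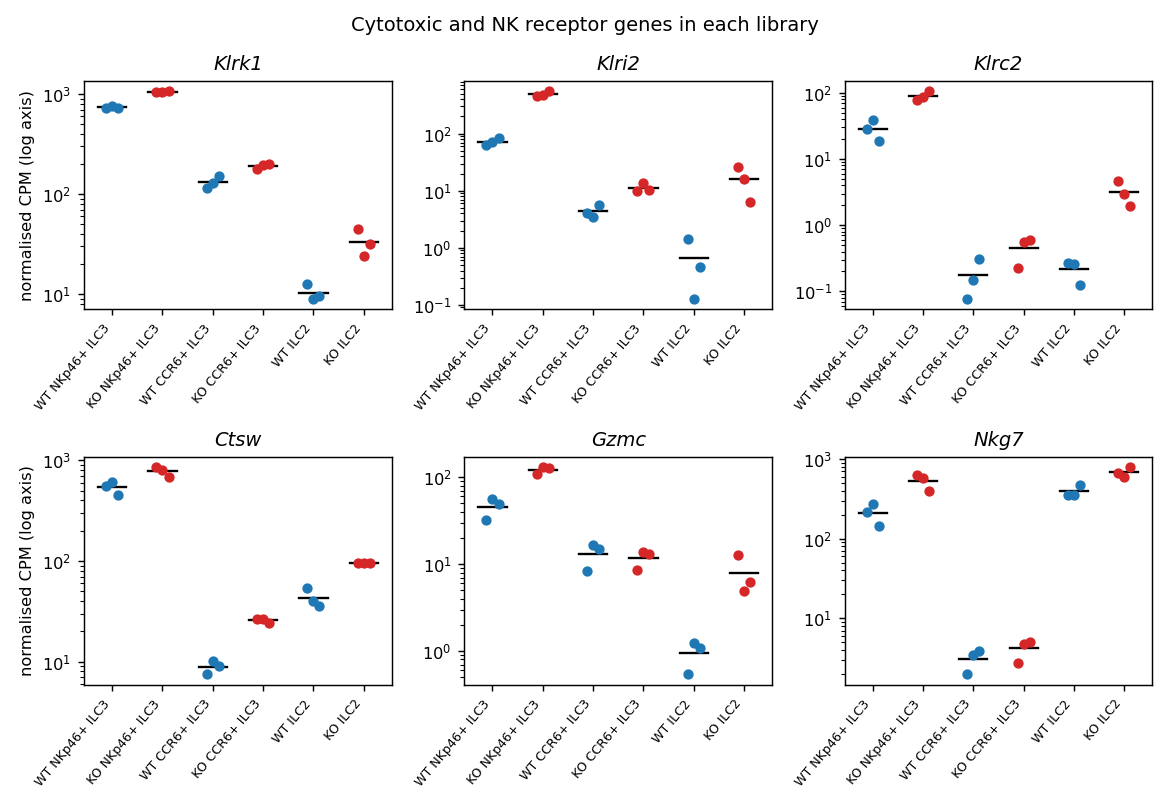
Normalised CPM on log axes of Klrk1, Klri2, Klrc2, Ctsw, Gzmc and Nkg7 in each library; blue points are WT, red points are KO and black lines are group means, with a library at zero not drawn. In ILC2, Klrk1 has a mean of 10.4 CPM in WT and 33.5 CPM in KO.

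The KO effects of the 3 subsets overlapped by direction. They share no libraries, but same-numbered libraries of different subsets need not be independent, since those of KO CCR6+ ILC3 and KO ILC2 deviated together (correlations 0.155, 0.235 and 0.216). So did 2 of 3 between KO NKp46+ and KO CCR6+ ILC3 (0.373 and 0.324, with -0.0171 in the other) and those between WT NKp46+ and WT CCR6+ ILC3 (0.0974, 0.196 and 0.313). Between KO NKp46+ ILC3 and KO ILC2 the correlations were 0.139 and 0.111 for numbers 2 and 3 and 0.0174 for number 1. Those of WT ILC2 with the WT ILC3 subsets ran from -0.172 to 0.118. Between NKp46+ and CCR6+ ILC3, 23 genes were higher in both where 0.661 would be shared by independent lists (Fisher's exact p = 8.5e-30), and 69 lower in both where 2.62 would be (exact p = 9.28e-82). Rcn1 and Bmp2, named after their values were seen, were higher in NKp46+ and lower in CCR6+ KO cells, where 1.75 would be for independent lists (exact p = 0.695), and none moved the other way. NKp46+ ILC3 and ILC2 shared 9 higher genes (0.430 for independent lists, exact p = 3.83e-10) and 16 lower genes (0.477, exact p = 4.33e-21). CCR6+ ILC3 and ILC2 shared 4 higher (0.277, exact p = 0.000167) and 14 lower genes (0.543, exact p = 8.19e-17). In opposite directions, Vipr2 and Cyth3 were higher in NKp46+ ILC3 and lower in ILC2 (0.319 for independent lists, exact p = 0.0403, adjusted p = 0.0692), Cyth3 was also higher in CCR6+ ILC3 and lower in ILC2 (exact p = 0.186), and no gene was lower in an ILC3 subset and higher in ILC2. The largest p-value of the overlaps in the same direction was 0.000334 when adjusted over the 12 overlaps tested, and genes are not independent replicates, nor are the libraries shown to be. Called in all 3 subsets were Usp18, which rose, and 12 genes that fell, among them Maf, Itga4, Ccr9, Podnl1, Rnase4 and Sntb1. Stab2, Gm16271 and 1700113H08Rik, also among the 12, start within 1 Mb of each other on chromosome 10. Usp18, Podnl1, Ccr9 and Pi4k2a each start within 1 Mb of another gene shared by at least 2 subsets. Strain segments therefore stay open for these shared genes. Itga4, Ppm1l, Timp2, Rnase4 and Sntb1 had no such neighbour. With only the groups compared, Usp18 and Ccr9 were not called in CCR6+ ILC3 (adjusted p = 0.075 and 0.0623), nor Podnl1 and Rnase4 in ILC2 (0.163 and 0.212), and Rnase4 in ILC2 was at 0.0587 without KO ILC2 replicate 2. In all, 109 genes moved the same way in at least 2 subsets. This count was 67 and 72 without WT NKp46+ replicates 1 and 3, 68 and 55 without WT CCR6+ replicates 2 and 3, and 65 without KO CCR6+ replicate 2.

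The KO effects also differed between subsets, in tests of the difference itself. The effect on Bmp2 was higher in NKp46+ than in CCR6+ ILC3 by 2.86 ± 0.28 on the log2 scale (adjusted p = 0.000219), and that on Relt by 2.15 ± 0.21 (adjusted p = 0.000219). Against ILC2, the effects on Tmem64 and Ffar2 were lower in NKp46+ ILC3 by log2 differences of -1.32 (adjusted p = 8.78e-05) and -2.41 (adjusted p = 0.000109), and in CCR6+ ILC3 by -1.23 (adjusted p = 0.000219) and -2.22 (adjusted p = 0.000487). The effect on Sntb1 was less negative in NKp46+ ILC3 than in ILC2 by 3.27 (adjusted p = 0.000259) and in CCR6+ ILC3 by 2.39 (adjusted p = 0.00662). Vipr2 rose in KO NKp46+ ILC3 (1.02 ± 0.15, adjusted p = 0.00106) and fell in KO ILC2, a difference of 2.19 (adjusted p = 9.92e-05).

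The difference between the KO effects of NKp46+ and CCR6+ ILC3 was called for 25 genes, that between NKp46+ ILC3 and ILC2 for 59, and that between CCR6+ ILC3 and ILC2 for 53. Of these, 18, 26 and 12 had the higher effect in the subset named first, or 72.0%, 44.1% and 22.6%. With scaling to library totals the shares were 83.3%, 55.2% and 38.6%, a scaling that moved the median of all genes by 0.105 (log2) in the last of these differences. The count of 25 was 7, 14 and 8 without WT NKp46+ replicates 1, 2 and 3, 10 without WT CCR6+ replicate 2 or 3, 11 without KO CCR6+ replicate 1 or 2 and 15 without KO NKp46+ replicate 3. The count of 59 was 39 without WT NKp46+ replicate 3. The count of 53 was 26 and 29 without WT CCR6+ replicates 2 and 3, 34 without KO CCR6+ replicate 2 and 33 without KO ILC2 replicate 2.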

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

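The differences between subsets below came from tests fixed before the data were examined, and so did those of the Maf segment, of sex and of the shift between ILC3 subsets; the tests of pairs of neighbouring genes and of NKp46+ ILC3 within the KO sorts, and the values of the shift that allow for same-numbered libraries, were chosen only after the results were seen.

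The KO effect differed between NKp46+ and CCR6+ ILC3 for 25 genes. Its log2 difference, NKp46+ minus CCR6+, was 2.15 for Relt and 2.86 for Bmp2 (both adjusted p = 0.000219), 1.74 for Ikzf3, 1.61 for Ptger4, a prostaglandin receptor gene, and 4.05 for Pvrig (all adjusted p = 0.00657). It was -1.52 for Sema4b (adjusted p = 0.0114), -3.21 for Tcrg-C2 (0.0247), -6.88 for Spp1 (0.0371), -1.58 for Tspan32 (0.04), -1.20 for Dkkl1 (0.0494) and 3.15 for Il17rb (0.0288). Sema4b lost its call without WT NKp46+ replicate 1 (adjusted p = 0.0508). Tcrg-C2 lost it without any WT NKp46+ library, WT CCR6+ replicates 2 or 3, KO NKp46+ replicate 1 or KO CCR6+ replicates 1 or 2 (highest 0.08). Il17rb lost it without WT NKp46+ replicates 1 or 3, any WT CCR6+ library or any KO CCR6+ library (highest 0.1). Spp1 kept its call only without KO NKp46+ replicate 3 or KO CCR6+ replicate 1 (highest 0.141 otherwise), Tspan32 only without KO NKp46+ replicates 1 or 3 (0.129) and Dkkl1 only without KO NKp46+ replicates 2 or 3 (0.149). With only the groups compared, Spp1, Tspan32 and Dkkl1 (each 0.0944) and Il17rb (0.0655) were not called, nor were Spp1 (0.0826), Tspan32 (0.108) and Il17rb (0.0778) without the filter. Tspan32 was at 0.0653 with library totals, and Dkkl1 at 0.0672 with the replicate block and 0.119 with that block within genotype.

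Between NKp46+ ILC3 and ILC2 the KO effect differed for 59 genes. The log2 difference, NKp46+ minus ILC2, was 2.19 for Vipr2 (adjusted p = 9.92e-05), 3.27 for Sntb1 (0.000259), 2.50 for Bmp2 (0.000494), 1.86 for Pheta2 (0.00383), 2.16 for Dgat2 (0.0356) and 1.61 for Tcf7 (0.0108). It was -1.32 for Tmem64 (8.78e-05), -2.41 for Ffar2 (0.000109), -2.91 for Vill (0.00179), -3.96 for Dppa2 and -1.69 for Sema4b (both 0.00327), -1.26 for Lif (0.013), -1.38 for Hes1 (0.0113) and -1.20 for Icos (0.0293). Nckap5 had a fitted difference of 8.59 (adjusted p = 0.0108) and was at 0 CPM in all WT NKp46+ libraries, so this value depends on the default prior count of the fit and is no bound. Icos kept its call only without WT ILC2 replicate 1, KO ILC2 replicate 1 or KO NKp46+ replicate 2 (highest adjusted p = 0.0899 otherwise), and Dgat2 only without WT NKp46+ replicate 1 or KO ILC2 replicate 3 (0.0909). Dgat2 also lost its call with the replicate block (0.0599), without the filter (0.125) and with only the groups compared (0.0512), and Tcf7 with only the groups compared (0.0618).

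Between CCR6+ ILC3 and ILC2 the KO effect differed for 53 genes. The log2 difference, CCR6+ minus ILC2, was 2.39 for Sntb1 (adjusted p = 0.00662), 1.67 for Cyth3 (0.00915), 2.27 for Ldhb (0.0107), 1.55 for Tcf7 (0.0154) and 3.01 for Tcrg-C2 (0.0184). It was -1.23 for Tmem64 (0.000219), -2.22 for Ffar2 (0.000487), -3.82 for Ltb4r1, a leukotriene receptor gene (0.00109), -1.71 for Relt (0.00158), -4.06 for Dppa2 (0.00403), -1.40 for Icos (0.0125), -3.22 for Gzmc (0.0154), -1.03 for Cxcr6 (0.0271) and -1.07 for Il12rb1 (0.0432). Calls ended for Tcf7 without WT CCR6+ replicate 2 or KO ILC2 replicate 2 (highest adjusted p = 0.0579), for Tcrg-C2 without WT CCR6+ replicates 2 or 3 or KO ILC2 replicate 1 (0.0695) and for Gzmc without WT CCR6+ replicate 2 (0.0507). Cxcr6 kept its call only without WT CCR6+ replicate 3, WT ILC2 replicate 1, KO CCR6+ replicate 1 or KO ILC2 replicate 3 (highest 0.0883 otherwise), and Il12rb1 only without WT CCR6+ replicate 1 (0.135). With only the groups compared, Tcf7 (0.0796), Tcrg-C2 (0.0705), Gzmc (0.0705), Icos (0.0616), Cxcr6 (0.0956) and Il12rb1 (0.145) were not called. Without the filter Tcf7 was at 0.0594 and Gzmc at 0.056, and with library totals Cxcr6 was at 0.154.

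Other splits of the libraries were counted for each comparison. The KO comparisons and the WT ILC3 comparison allow 10 splits each, too few for a share under 0.05. The real split called 322, 303, 94 and 2745 genes in NKp46+ ILC3, CCR6+ ILC3, ILC2 and WT ILC3, and the highest other split 1, 0, 7 and 0. For WT ILC2 against ILC3, 60 splits were drawn with the real one among them. Only the real one gave as many as its 5230 genes, a share under 0.05. This excludes chance only if the libraries are independent samples, which the labels do not say. The highest other split gave 4380 and kept all 3 ILC2 libraries together. For the differences of the KO effect, 6, 5 and 4 of 60 splits drawn likewise gave as many genes as the real 25, 59 and 53, with highest others of 184, 128 and 128, so chance was not excluded for these counts. The splits that called the most exchanged 2 of 3 WT with 2 of 3 KO libraries within 1 subset, which adds the effects of both subsets instead of subtracting them, and so points to the structure of the samples.

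Apart from Maf, 108 genes moved the same way in at least 2 subsets. A strain segment carried with the floxed allele would raise the share of these genes near Maf. Of 198 genes within 10 Mb of Maf 1 was among them (Plcg2), and of 15993 elsewhere 107 (Fisher's exact p = 1). The window was thus not enriched, which says nothing on the source of the genes elsewhere. With so few genes in the window the test cannot exclude a segment that alters a few of them. In that window 10 genes were called in at least 1 subset. A segment wider than the window was not tested. Podnl1 and Samd1 lie outside it on the chromosome of Maf (chromosome 8, starts 84125989 and 83997672, with Maf at 115682942). A different sex make-up was argued against, since 0 sex-linked genes were called and the Y-linked genes summed to at most 0.451 CPM in every library, with Xist at 74.4 to 180 CPM. Segments elsewhere in the genome stay open. The genes formed 15 pairs within 1 Mb against a median of 9 and a 95th percentile of 16 in 10000 random draws (permutation p = 0.0834, one-sided), and the incomplete backcross may leave such segments. Among the pairs are Stab2 on chromosome 10 (86841198 to 87008025), which went from a mean of 31.4 CPM in WT to 0 CPM in all KO NKp46+ libraries and was lower in all 3 subsets, and its antisense neighbour, whose reads cannot be told apart from it, while an effect of Maf on these genes also stays open.

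Cytotoxic and NK receptor genes rose in KO ILC2, and NKp46+ ILC3 within the KO ILC2 sort are a candidate source that cannot be told apart from a change within ILC2, although a complete KLRG1 gate would remove them (Klrg1 was at 9.73 CPM in WT NKp46+ ILC3 and 846 CPM in WT ILC2). A strain segment also stays open for Klrc2 and Klri2, which start within 1 Mb of each other on chromosome 6 (129647496 and 129729041). The test of neighbouring genes took only genes shared by at least 2 subsets. It did not cover Klrk1, Klrb1c, Klrc1 and Gzmc, so a segment stays open for these as well. The 50 most abundant genes at least 16 times higher in KO NKp46+ ILC3 than in WT ILC2 moved by an amount that a median admixture of 2.00% would give (quartiles 1.11 and 2.68, 47 above 0), while the 8 called genes needed 3.34% (quartiles 2.93 and 4.94). Of these 8 genes 5 are among the 50 markers (Ctsw, Klrk1, Klrb1c, Klrc1 and Klri2), and the other 45 markers gave 1.74% (quartiles 1.07 and 2.60, 42 above 0). The quartile ranges were apart by 0.245 percentage points, or 0.325 without those 5 genes, which met the bound set for excluding admixture, but either gap was small beside the spread of the markers, and the requirement of a wider gap was made after the values were seen. Per library the estimate from all 50 was 3.16%, 2.16% and 0.579% in KO and 0.558%, -0.0310% and -0.753% in WT. KO replicate 3 still held Klrk1 at 31.7, Ctsw at 96.0 and Klri2 at 6.42 CPM. Rorc (24.1 in WT, 23.9 CPM in KO) did not follow an admixture, its WT level being too variable to exclude one. Il1r1 (4.19 and 4.08 CPM) and Serinc2 (8.28 and 7.97 CPM) did not rise either. Il22 rose by as much as 0.335% would give, with 47 of the 50 markers above 0.

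The KO effect in CCR6+ ILC3 was set against the WT difference between NKp46+ and CCR6+ ILC3, with a shift of Maf-deficient CCR6+ cells towards the NKp46+ profile as the biological hypothesis. The covariance over all genes was 0.164 (r = 0.195), below the 0.211 to 0.266 that the shared WT CCR6+ libraries gave in 100 simulations without any effect, a bound set for arguing against a shift that took all libraries as independent. The replicate spread of the WT CCR6+ libraries by itself gave 0.242 in the simulations and 0.199 in the real data. The simulated range is therefore too high. Same-numbered WT NKp46+ and WT CCR6+ libraries deviated together, and without any effect the replicates then give 0.157, or 0.138 with the KO CCR6+ libraries treated likewise, while libraries of different number gave a mean covariance of 0.0254 (-0.332 to 0.445 over 18 combinations), so a shift is neither shown nor excluded. Called genes pointed both ways, with 28 higher in KO and in NKp46+ cells (7.94 for independent lists) but 84 lower in KO and higher in NKp46+ cells (21.0), 35 lower in both (16.3) and 19 higher in KO and lower in NKp46+ cells (6.14). The shared WT CCR6+ libraries enter both differences with the same sign. They can therefore add to the 28 and 35 genes but not to the 84 and 19. NKp46+ ILC3 within the KO CCR6+ sort, whose gate for CCR6 without NKp46 would remove them, were argued against for the 28 genes as a set. The 50 markers gave a median of 0.741% (quartiles 0.0269 and 4.06), while the 28 genes needed 44.2% (quartiles 30.6 and 65.3). Among the markers were 10 immunoglobulin genes and 1 of the 28 genes (Ctsw, with a median of 0.651% without it). Ctsw itself needed 2.18%, within the marker quartiles, so admixture stays open for its rise. Tbx21 (1.62%), Klri2 (1.42%) and Klrb1c (1.37%), markers that were not called, gave similar shares, while Ncr1 gave 0.429% and Nkg7 0.206%.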

How the results depend on the processing

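The tests that left out 1 library from the list comparisons and from the overlap between subsets were chosen after the results were seen; all others were fixed beforehand. No call of a named gene reversed: over all alternatives 13592 comparisons of named genes kept their side of the threshold, 286 lost and 145 gained a call. Of the lost calls 209 came from leaving out a library, 44 from fitting only the groups compared and 21 from no expression filter. List tests kept their side 1155 times, lost a call 72 times, 31 of them with an estimated correlation, gained one 44 times and reversed 1 time, for the gating genes in WT ILC3, which fry placed lower in NKp46+ cells at adjusted p = 0.0304.

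Counts of called genes in the KO comparisons of NKp46+ ILC3, CCR6+ ILC3 and ILC2 were 726, 730 and 288 with DESeq2. It held 322 of 322, 302 of 303 and 93 of 94 of the edgeR calls. DESeq2 made more false calls on simulated data, which were drawn with edgeR's own estimates of spread and do not rank the methods on the real libraries. They were 135, 105 and 32 at an adjusted p under 0.01, and 161, 125 and 53 with an absolute log2 change of at least 1, both stricter by construction. With only the groups compared they were 304, 209 and 30, a setting with fewer samples to estimate the spread. That setting held 197 of 322, 131 of 303 and 21 of 94 of the main calls. The WT ILC3 comparison gave 1623 at the lower threshold and 1270 with the minimum change, and WT ILC2 against ILC3 gave 2534 with the minimum change. The 3 differences of the KO effect (NKp46+ minus CCR6+, NKp46+ minus ILC2, CCR6+ minus ILC2) were called for 170, 258 and 233 genes with DESeq2, 6, 14 and 13 at the lower threshold and 38, 37 and 21 with only the groups compared, where the cause was not tested. Genes shared by at least 2 subsets numbered 262 with DESeq2 and 38 at the lower threshold.

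Leaving out each library in turn gave 176 to 254 genes in KO NKp46+ ILC3, 117 to 251 in KO CCR6+ ILC3 and 52 to 104 in KO ILC2. It gave 1968 to 2264 in WT ILC3, 4117 to 4899 in WT ILC2 against ILC3, 7 to 25, 39 to 80 and 26 to 61 for the 3 differences, and 55 to 111 for the genes shared by subsets. The libraries behind the lower values are named with each result in the report, and a fit with fewer libraries has less power by construction. At this depth and n = 3, changes near log2 1 are often missed, with 54% to 60% recovered in simulated KO comparisons.

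With the replicate number as a block, 355, 331 and 96 genes were called in the 3 KO comparisons and 129 were shared. Same-numbered WT and KO libraries did not deviate together (correlations -0.240 to 0.173), so the numbers were not taken to pair the samples. Same-numbered KO CCR6+ ILC3 and KO ILC2 libraries did (0.155, 0.235 and 0.216, each highest with its own number), and WT NKp46+ and WT CCR6+ ILC3 at 0.0974, 0.196 and 0.313, a hint from the data only. The block ended the calls of the LTi and erythroid lists in KO NKp46+ ILC3 (adjusted p = 0.0713 and 0.0527) and of 5 named genes, Cd69 in KO ILC2 (0.063), Xist (0.0577) and Rpl22l1 (0.0509) between the WT ILC3 subsets, and Dkkl1 (0.0672) and Dgat2 (0.0599) in the differences of NKp46+ ILC3 from CCR6+ ILC3 and from ILC2.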

Other observations

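No test of a hypothesis is added in this part; the list tests below were fixed before the data were examined, and leaving out single libraries from them was added after.

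In WT ILC2, 51 of 78 ribosomal protein genes were higher than in the ILC3 subsets and 1 was lower (camera adjusted p = 2.99e-16, adjusted p = 0.200 with an estimated correlation), as were 8 of 14 mitochondrially encoded genes (0.00397; 0.408 with an estimated correlation). Cholesterol synthesis genes were higher in ILC2 for 7 of 14 and lower for 1 (0.00156; 0.219 with an estimated correlation), with Cyp51 higher by 2.47 ± 0.13 (adjusted p = 8.05e-10). Type 1 (3 higher, 11 lower of 23), cytotoxic (4 and 16 of 25) and type 3 genes (3 and 13 of 18) were lower in ILC2 at 0.00117, 7.47e-06 and 7.47e-06, which became adjusted p = 0.131, 0.131 and 0.0570 with an estimated correlation. Nkg7 went the other way and was higher in ILC2 by 3.95 ± 0.24 (adjusted p = 5.73e-09) than the mean of the ILC3 subsets. That mean is lowered by WT CCR6+ ILC3, at 3.11 CPM, so the difference from NKp46+ ILC3 alone is smaller. Proliferation genes (4 of 22 higher, 0.0422; adjusted p = 0.696 with an estimated correlation) lost their call without WT NKp46+ replicate 1 or 3, WT CCR6+ replicate 1 or WT ILC2 replicate 3 (highest 0.321). Markers of other cells also differed, although camera called neither list. Of 11 B and plasma cell markers 5 were lower in ILC2 (Cd79a, Jchain, Mzb1, Igha and Igkc) and 1 was higher (Ighm; list adjusted p = 0.373), with shares of 1.53% of counts in WT ILC2, 3.77% in WT NKp46+ and 4.86% in WT CCR6+ ILC3. Of 11 T cell markers 4 were higher (Cd3g, Trbc1, Trbc2 and Themis; list 0.0840, and 0.0465 with fry), with shares of 0.0580%, 0.0337% and 0.0157%. Tcf7 was lower in ILC2 by a log2 difference of -2.82 ± 0.19 (adjusted p = 7.5e-09).

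Between the WT ILC3 subsets, further lists passed camera and lost their call with an estimated correlation. Higher in NKp46+ cells were cholesterol synthesis (8 of 14 genes, adjusted p = 0.210 with an estimated correlation), proliferation (6 higher and 1 lower of 22, 0.256), T cell markers (4 of 11, 0.256), residency genes (8 and 1 of 16, 0.113), glycolysis (7 and 1 of 16, 0.256), Maf-associated coinhibitory genes (5 and 2 of 13, 0.210), Notch genes (2 of 8, 0.225) and interferon response genes (6 and 2 of 24, 0.590). Lower were type 3 genes (2 higher and 7 lower of 18, adjusted p = 0.225 with an estimated correlation) and MHC class II genes (1 of 11 lower, 0.457). The Notch call ended without WT CCR6+ replicate 1 or WT NKp46+ replicate 3 (highest adjusted p = 0.131), and the interferon call without WT CCR6+ replicate 1 (0.199). Irf7, an interferon-induced transcription factor gene, was higher in NKp46+ cells by 2.76 ± 0.25 (adjusted p = 1.99e-06), while Usp18 was lower (-1.40 ± 0.20, adjusted p = 0.000103).

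Lists without a called direction in any KO comparison, with camera adjusted p in NKp46+ ILC3, CCR6+ ILC3 and ILC2, were the type 1 program (0.173, 0.957, 0.0523), MHC class II (0.892, 0.469, 0.771), naive-like and TCF1-associated genes (0.0505, 0.591, 0.827), immediate early and stress genes (0.755, 0.113, 0.269), the interferon response (0.905, 0.185, 0.475), Maf-associated genes (0.585, 0.106, 0.539), mitochondrially encoded genes (0.585, 0.113, 0.878), the gating genes (0.246, 0.427, 0.228), and markers of T cells (0.572, 0.544, 0.757), B and plasma cells (0.113, 0.0926, 0.143), myeloid cells (0.625, 0.304, 0.269), epithelium (0.639, 0.222, 0.539) and stroma and endothelium (0.18, 0.427, 0.143). No list that camera called had a median, mean and test of different sign, while some that were not called did, such as the Notch genes in KO NKp46+ ILC3 (median log2 change 0.13, mean -0.03, test lower). Of the sex-linked list only Xist passed the expression filter, and it was not called in a KO comparison. Myeloid markers took 0.0425% to 0.142% of counts, highest in KO CCR6+ replicate 3. That library stood apart on the third principal component, with 6.63% of the variance (102, against 10.8 and 6.01 in the other KO CCR6+ libraries). WT NKp46+ replicate 3 and KO NKp46+ replicate 2 also stood apart, at -57.2 and -57.5 on the third component (-8.45 to 23.2 in the other NKp46+ libraries) and at 36.7 and 30.2 on the second (79.1 to 109), which held 18.1% of the variance. The KO count of 322 genes in NKp46+ ILC3 was 187 without the first and 205 without the second of these. Replicate 3 of both ILC2 groups was at 36.5 (WT) and 27.8 (KO) on the third component, and the other ILC2 libraries at -30.6 to -9.77.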
